A study of Homo sapiens with 6 samples.

How the data were processed

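Total RNA of MDA-MB-468 cells was made into stranded mRNA libraries with a TruSeq kit, per the labels' protocols, from 3 samples with Cas9 and a PRMT1 guide and 3 with Cas9 and a control guide. The deposited values are FPKM (fragment counts scaled by transcript length and by library size), as the file's column names state, with 1 row per identifier. Most identifiers are RefSeq transcripts, but 7240 begin with gene (8.50% of FPKM), 3313 with rna and 585 with id. The submitters' processing notes list bcl2fastq, Trimmomatic 0.38, HISAT2 2.1.0, StringTie 2.1.3b and the build GRCh38, without saying which step each performed. The RefSeq release and any filter are not given in the sources used here. FPKM shares 1 total among all transcripts, so a library with more mitochondrial RNA has lower FPKM elsewhere, and splitting of reads between transcripts of a gene adds error to transcript rows that a sum per gene partly removes.

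Transcript identifiers were matched to gene symbols through a RefSeq gene table of GRCh38.p14 (117389 identifiers), a GENCODE release 29 table (201) or a symbol within the identifier (10061), after a copy suffix had been removed from 83 identifiers. Unmatched were 42671 identifiers, which held 3.63% of FPKM and were tested apart. Values of matched identifiers were summed per symbol. Apart from 69748 rows at 0 in all libraries, all 6 values repeated those of another identifier in 207 cases, and these were kept. At most 0.0168% of tested genes had equal values (within 1e-06) in any pair of libraries, so all 6 counted as replicates. Correlations across genes of log2 values ranged from 0.989 to 0.992 within groups and from 0.974 to 0.977 between groups.

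Genes with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using eBayes with an intensity trend and no replicate block, and called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale understate the change of low genes, and n-fold values of genes in the text are ratios of mean FPKM, while n-fold values of blocks and counts of genes changed at least 2-fold are on the log2 scale with its pseudocount. Gene lists (35, fixed before the data were examined, of which 32 had at least 5 tested members) were tested with limma's camera at a preset correlation of 0.01, then with an estimated correlation and with fry, each adjusted over the lists. In all, 15 lists were called with the preset value, 0 with an estimated correlation and 18 by fry. The directional p of fry asks whether the genes of a list move on balance one way. It does not compare them with other genes. The estimated correlation was 0.504 for ribosomal proteins and 0.313 for hypoxia genes. For RNA-binding proteins (0.00965) and NF-kB targets (-0.0329) it lay below the preset value. A higher correlation therefore does not account for the loss of those calls. The test direction and the median differed in sign for the pentose phosphate and ATF4 lists, the mean and median for p53 targets, and camera and fry for the NRF2 and p53 lists.

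Named genes followed a rule fixed before the data were examined: PRMT1 and 14 other stated genes, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 FPKM and groups that did not overlap, and in each list up to 2 called members with the largest rise and 2 with the largest fall. The largest rises and falls left out clone-style, pseudogene and readthrough symbols and those starting with LOC, LINC, MIR, SNOR or RNU, but not transfer RNA genes. PRMT1 was also tested with an exact two-sided permutation test over 20 arrangements. Alternatives were other pseudocounts, filters, scalings and eBayes settings, a replicate block, 1 transcript per gene, and leaving out each library in turn. Added after the data had been seen were a test without the genes of the chromosome blocks, one without mitochondrial genes and one without control replicates 2 and 3 together.

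The block search and its settings were chosen after the data had been seen. Blocks of neighbouring genes were sought by recursive segmentation along each chromosome, where each step cut out the stretch that differed most from the rest. The values were log2 fold changes of 8641 protein-coding genes with a mean of at least 3 FPKM, limited to 1.5 in size. A stretch cut out needed at least 10 genes. Each step used 200 permutations and a p of at most 0.005. A block needed at least 20 genes and a median of at least 0.25 log2 units in size. In simulated data for the comparison, on 11883 genes with 200 changed per set and 5 sets, limma recovered 78.8% of genes changed by 0.585 log2 units, 93.5% of those changed by 1 unit and 98.8% of those changed by 2 units, and 5.20% of called genes had not been changed. The 200 genes were drawn only from more abundant genes, above a floor higher than the 1 FPKM needed for testing. Recovery among lower genes was therefore not measured. Across the simulated sets camera called 2 lists that had not been planted. The simulated noise was independent between genes, so this count does not cover lists whose genes vary together. The block search gave 0 blocks in 3 sets of randomly ordered genes and found all 3 planted blocks of 60 genes shifted by 0.5 log2 units. Weaker or shorter shifts were not planted, so their recovery was not measured. Random order also breaks up any shared regulation of neighbouring genes, so blocks from that source were not counted. Segmentation and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Levels of near-identical copies (histones, keratins, HLA genes, ribosomal proteins with many pseudogenes) are uncertain, because the handling of shared reads is not given in the sources used here.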

Results

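Gene expression was measured by RNA sequencing in MDA-MB-468, an established triple-negative breast cancer cell line, after Cas9 had been introduced together with a guide RNA against PRMT1 or with a control guide. PRMT1 encodes the main type I protein arginine methyltransferase, which places asymmetric dimethyl marks on arginines of histones and RNA-binding proteins. Each group held 3 libraries, labelled replicates 1 to 3. The stated purpose was to examine the role of PRMT1 in metabolic remodelling, in the setting of chemoresistance. The values were FPKM for 170322 rows, mostly transcripts, which were summed to 42101 gene symbols, and 11883 genes with a mean of at least 1 FPKM over the 6 libraries were tested. Total FPKM per library ranged from 366108 to 386363. Read depth is unknown, because the values are already divided by depth and no whole-read steps were visible among low values: at most 2.96% of the ratios between any pair of libraries fell in one bin of 0.05 log2 units. Transcripts of the mitochondrial genome held 7.04% to 7.15% of FPKM in the PRMT1 guide libraries and 7.18% in control replicate 1, but 10.5% in control replicate 2 and 13.7% in control replicate 3.

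PRMT1 mRNA did not differ detectably between the groups. It measured 56.6 ± 10.5 FPKM with the PRMT1 guide and 63.8 ± 13.4 FPKM with the control guide (SD, n = 3 each; exact permutation test, two-sided p = 0.7, where 0.1 is the smallest p that 3 against 3 can give). The log2 fold change was -0.16 ± 0.18 (SE; limma adjusted p = 0.548), with a 95% interval from -0.58 to 0.25 by limma and from -0.81 to 0.48 from the spread of PRMT1 alone. The gene lies on chromosome 19 from 49676153 to 49688447 (GRCh38.p14). Small insertions and deletions at a Cas9 target site need not lower an mRNA, and the position of the guide within the gene is not given in the sources used here. The mRNA level therefore does not check the labels in either direction, and protein was not among the data used here. Of the main transcripts, NM_198318 measured 34.1 ± 12.9 against 39.5 ± 12.7 FPKM, NM_001536 measured 19.1 ± 1.43 against 16.7 ± 1.94 FPKM, and the non-coding NR_033397 measured 3.08 ± 2.22 against 7.01 ± 1.64 FPKM.

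Of the other arginine methyltransferases, 2 were called, both lower. PRMT6, which methylates histone H3, fell 1.26-fold to 11.9 ± 0.701 FPKM (log2 fold change -0.31 ± 0.06, limma adjusted p = 0.0120), although the adjusted p for PRMT6 was 0.0522 without PRMT1 guide replicate 1 and 0.190 without control replicates 2 and 3. PRMT9 fell from 1.73 ± 0.189 to 0.854 ± 0.0762 FPKM (2.02-fold; log2 fold change -0.56, limma adjusted p = 0.00397), with an adjusted p of 0.0917 for PRMT9 when the most abundant transcript stood for the gene. CARM1 measured 19.3 against 16.7 FPKM (limma adjusted p = 0.0530), and PRMT2, PRMT3 and PRMT5 had adjusted p of 0.778, 0.434 and 0.496. Of 8 measured family members 0 rose and 2 fell (1 and 2 adjusted over the list alone), and the family as a list was not called (camera adjusted p = 0.573).

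**Figure D1:**
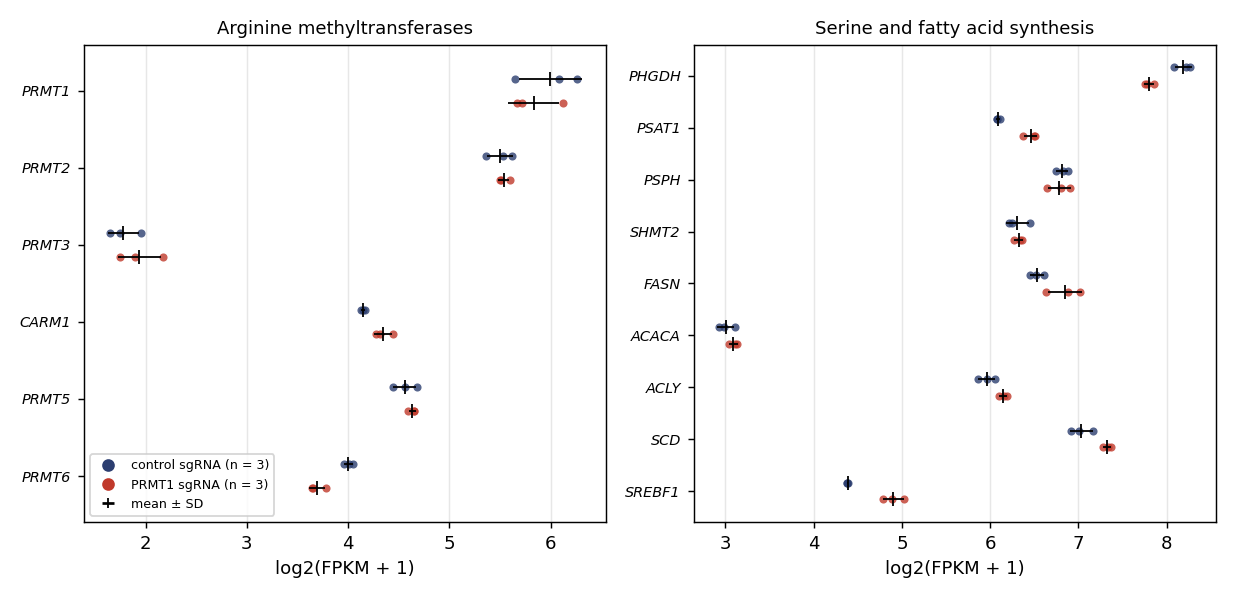
Levels of arginine methyltransferase genes (left) and of enzymes and a regulator of serine and fatty acid synthesis (right) as log2(FPKM + 1), with 1 point per library (n = 3 per group) and black marks for mean ± SD. PRMT1 overlaps between the groups, while PHGDH lies lower and PSAT1 and SREBF1 lie higher in every PRMT1 guide library.

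Some changes were large among called genes whose groups did not overlap, which the rule for naming required. XAGE2, a cancer-testis antigen, measured 32.1 ± 0.778 FPKM with the PRMT1 guide against 1.32 ± 0.539 FPKM (24.3-fold; log2 fold change 3.86 ± 0.15). SLC34A2, a sodium-phosphate cotransporter, rose from 2.08 ± 0.244 to 29.3 ± 0.689 FPKM, and S100A2, a calcium-binding protein of basal epithelium, from 7.22 ± 0.796 to 73.9 ± 1.95 FPKM. GLYATL2 rose from 15.3 to 138 FPKM, IGFBP5, an insulin-like growth factor binding protein, from 4.45 to 41.0 FPKM, and the imprinted gene PEG10 from 5.61 to 47.2 FPKM. MME, a cell-surface peptidase, and MMP7, a matrix metalloproteinase, rose 14.2-fold and 7.50-fold. AARD and LY6D rose 10.4-fold and 7.85-fold, and both lie in a stretch of chromosome 8 whose genes were higher as a group. Among the named genes the largest fall on the log2(FPKM + 1) scale was that of SCGB2A2, which encodes the secreted breast protein mammaglobin, from 215 ± 19.4 to 24.0 ± 0.208 FPKM (log2 fold change -3.11 ± 0.07). EGR1 and FOS, immediate early transcription factors, fell 9.95-fold and 5.96-fold, from 46.8 ± 8.78 to 4.70 ± 0.312 FPKM and from 8.85 ± 2.41 to 1.49 FPKM. FGG, the fibrinogen gamma chain, fell 12.3-fold and the secreted phospholipase PLA2G2A 7.24-fold. DKK1, a Wnt antagonist, CLDN10, a tight junction protein, and LDHB, a lactate dehydrogenase subunit, fell 4.61-fold, 3.37-fold and 4.69-fold. The LDHB call was lost when the most abundant transcript stood for the gene (adjusted p = 0.346). The last of the 10 were CA9, a carbonic anhydrase induced by hypoxia, which fell 4.09-fold, and the mitochondrial transfer RNA gene TRNF, which fell 3.66-fold but is too short for a reliable FPKM. For these 20 genes limma adjusted p ranged from 7.74e-07 to 0.00132.

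In all, 2820 genes were called by limma at an adjusted p under 0.05, 1376 higher and 1444 lower with the PRMT1 guide, and 177 of them changed by at least 1 log2 unit on the log2(FPKM + 1) scale, 110 higher and 67 lower. This count depends on the scale and the filter: genes called with at least 2-fold change numbered 319 with a pseudocount of 0.1 and 110 with a mean of at least 5 FPKM. Group ranges did not overlap for 41.6% of tested genes, where chance gives 10%. Genes called numbered 1697 without PRMT1 guide replicate 1 (genes called higher 847, genes called lower 850) and 1758 without control replicate 2 (genes called lower 830). Without both control libraries that had more mitochondrial RNA, genes called numbered 984, in a fit where the lone control library is assumed to vary like the other group. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these libraries. Nor do they say whether the cells of either guide were a pool or a single clone, so a fold change here is not separated from differences between clones.

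**Figure D2:**
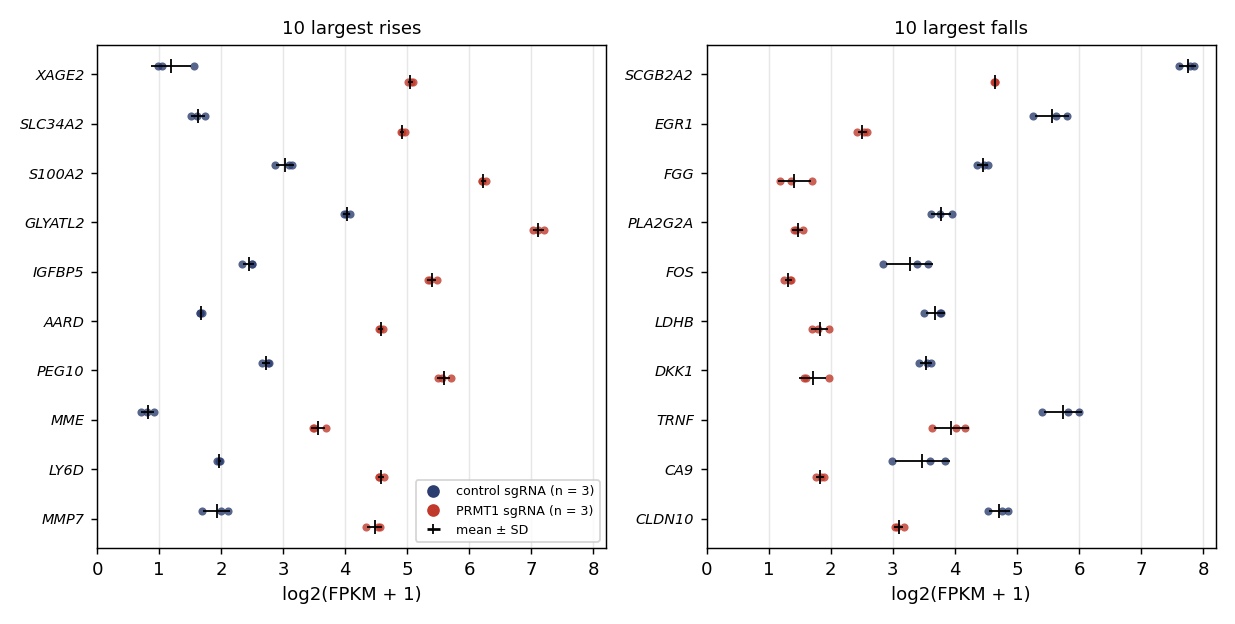
The 10 largest rises (left) and 10 largest falls (right) among called genes, as log2(FPKM + 1) with 1 point per library (n = 3 per group) and black marks for mean ± SD. Only genes with a mean of at least 5 FPKM and groups that did not overlap could be chosen.

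Serine and one-carbon metabolism, the question nearest to the stated purpose, moved upwards as a list, but its enzymes split. PHGDH, the first enzyme of serine synthesis, fell from 291 ± 18.8 to 221 ± 9.04 FPKM (log2 fold change -0.39 ± 0.06, limma adjusted p = 0.00489). The next enzyme, PSAT1, rose from 67.2 ± 1.01 to 87.0 ± 4.24 FPKM (log2 fold change 0.37 ± 0.05, limma adjusted p = 0.00279), with an adjusted p of 0.0676 without control replicates 2 and 3. PSPH and SHMT2 measured 109 against 112 FPKM and 79.2 against 78.4 FPKM (adjusted p = 0.796 and 0.885). The mitochondrial folate enzyme MTHFD1L rose 2.05-fold and the folate carrier SLC25A32 rose 1.67-fold, and both lie in shifted stretches of chromosomes 6 and 8 (adjusted p = 0.152 for SLC25A32 with the most abundant transcript). FOLR1, a folate receptor, fell from 2.89 to 1.25 FPKM (adjusted p = 0.0555 without PRMT1 guide replicate 1). Of 26 measured members 7 rose and 2 fell (8 and 2 adjusted over the list alone). The list was called higher (camera adjusted p = 0.0138), but adjusted p = 0.319 with an estimated correlation, and 0.0691 without control replicates 2 and 3.

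In fatty acid synthesis, SREBF1, the transcription factor that drives lipogenic genes, rose 1.46-fold from 19.9 ± 0.135 FPKM (log2 fold change 0.52 ± 0.07, limma adjusted p = 0.00195), and ACSL1, which activates long-chain fatty acids, rose 1.65-fold (adjusted p = 0.450 for ACSL1 with the most abundant transcript). SCD, the stearoyl-CoA desaturase, rose from 130 ± 11.8 to 159 ± 5.38 FPKM (adjusted p = 0.0246). That call was lost without PRMT1 guide replicate 1 or 3 or control replicate 1 or 3, at SCD adjusted p from 0.0565 to 0.0815. FASN measured 115 against 91.4 ± 5.19 FPKM (log2 fold change 0.32 ± 0.10, limma adjusted p = 0.0529, and 0.0120 without PRMT1 guide replicate 3). ACLY and ACACA had adjusted p of 0.0677 and 0.427. ELOVL5, a fatty acid elongase, fell from 112 to 85.6 FPKM. Of 21 measured members 7 rose and 3 fell (10 and 4 adjusted over the list alone). The list was just called (camera adjusted p = 0.0487), with adjusted p = 0.319 with an estimated correlation. It kept its call in 7 of 20 settings (adjusted p from 0.0158 to 0.358) and lost it without PRMT1 guide replicate 1 or 3 or control replicate 1 or 3 (0.0608 to 0.0689), under each scaling tried (0.0515 to 0.0669), with genes of the shifted blocks left out (0.0537) and with the most abundant transcript (0.358).

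Among other metabolic lists, nucleotide synthesis was called higher (camera adjusted p = 0.0479; adjusted p = 0.415 with an estimated correlation), with 5 of 21 members higher and 2 lower (6 and 3 adjusted over the list alone). CTPS1, a CTP synthase, rose from 32.0 to 49.6 FPKM, and the ribonucleotide reductase subunit RRM2B, in the shifted part of chromosome 8, rose 1.78-fold. That list kept its call in 11 of 20 settings. Among the losses were those without PRMT1 guide replicate 1 (adjusted p = 0.0745), control replicate 1 (0.0546) or control replicate 3 (0.0608). The 13 measured protein-coding genes of the mitochondrial genome had a median log2 fold change of -0.55, yet 0 were called by limma (0 adjusted over the list alone). Their list was called lower (camera adjusted p = 0.0138), with adjusted p = 0.633 with an estimated correlation. This difference came from the control libraries: the median was -0.85 without control replicate 1 and -0.33 without control replicate 3 (adjusted p = 0.0714), and without control replicates 2 and 3 the median was 0.0146.

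Camera made no call for glycolysis (2 higher and 4 lower of 20; camera adjusted p = 0.254), where LDHA rose from 246 to 316 FPKM and PFKM, a phosphofructokinase, fell from 6.95 to 4.09 FPKM. Glycolysis was called lower without control replicates 2 and 3 (median -0.21, adjusted p = 0.0160). The tricarboxylic acid cycle (6 higher and 2 lower of 25; adjusted p = 0.131) included a rise of citrate synthase, CS, from 43.1 to 54.7 FPKM and a fall of IDH1 from 132 to 101 FPKM. Nuclear genes of oxidative phosphorylation (11 higher and 0 lower of 69; adjusted p = 0.0653) were led by CYC1 and NDUFB9, which rose 1.98-fold and 1.65-fold and lie in the shifted part of chromosome 8. This last list gained a call without PRMT1 guide replicate 1 (adjusted p = 0.0236) or 2 (0.0424), control replicate 2 (0.0288), or control replicates 2 and 3 together (0.0160). Fatty acid oxidation (0 higher and 5 lower of 21; adjusted p = 0.131), cholesterol synthesis (5 higher and 3 lower of 24; adjusted p = 0.131) and the pentose phosphate pathway (1 higher and 1 lower of 7; adjusted p = 0.877) were not called by camera either. By fry the tricarboxylic acid cycle was called higher (adjusted p = 0.0257) and fatty acid oxidation lower (0.0455). In the pentose phosphate pathway TKT, the transketolase, rose from 105 to 151 FPKM. Adjusted over the list alone, the counts higher and lower were 3 and 5 for glycolysis, 6 and 2 for the tricarboxylic acid cycle, 7 and 0 for oxidative phosphorylation, 0 and 5 for fatty acid oxidation, 7 and 3 for cholesterol synthesis and 1 and 1 for the pentose phosphate pathway.

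Most measured genes of basal epithelium rose, but KRT5 fell. KRT15 rose from 25.8 ± 2.08 to 93.4 ± 5.62 FPKM (log2 fold change 1.82 ± 0.07, limma adjusted p = 1.48e-05) and KRT16 from 7.56 to 21.1 FPKM, whereas KRT5, the usual basal marker, fell from 81.3 to 60.1 FPKM (adjusted p = 0.0505 without control replicate 3). Reads of type I keratins can be shared between near-identical copies, so their separate levels are uncertain. Of 14 measured members 10 rose and 1 fell (11 and 1 adjusted over the list alone), with a median log2 fold change of 0.59 (camera adjusted p = 1.19e-05; adjusted p = 0.319 with an estimated correlation). Luminal markers went both ways, with 4 higher and 8 lower of 19 (6 and 8 adjusted over the list alone; camera adjusted p = 0.437). ELF3 and MUC1 rose 1.79-fold and 1.80-fold, while XBP1 fell 1.66-fold and SPDEF fell from 110 to 73.4 FPKM. Of the mesenchymal genes 2 of 7 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.112, fry adjusted p = 0.00792), with fibronectin, FN1, higher 3.04-fold and TGFBI lower 1.84-fold.

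Genes of the unfolded protein response of the endoplasmic reticulum fell. XBP1, its central transcription factor, went from 314 ± 8.60 to 189 ± 8.21 FPKM (log2 fold change -0.73 ± 0.05, limma adjusted p = 0.000152), and PDIA4, a disulphide isomerase, from 70.5 to 46.2 FPKM. Of 18 measured members 0 rose and 10 fell (0 and 11 adjusted over the list alone; camera adjusted p = 0.000154; adjusted p = 0.319 with an estimated correlation). Hypoxia-responsive genes fell as well, 8 of 18 with 0 higher (8 and 0 adjusted over the list alone; camera adjusted p = 0.000267; adjusted p = 0.415 with an estimated correlation). EGLN3, a prolyl hydroxylase of the hypoxia pathway, went from 22.6 ± 4.55 to 9.58 ± 0.276 FPKM, and CA9 fell although it lies in a stretch of chromosome 9 where most genes were higher. The amino acid response driven by ATF4 was split, with 7 higher and 4 lower of 28 (7 and 5 adjusted over the list alone; camera adjusted p = 0.488), among them STC2 1.94-fold higher and DDIT4 1.54-fold lower.

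Proliferation and growth lists were called higher by camera at the preset correlation, though fry did not call G2 and mitosis (adjusted p = 0.123) or ribosomal proteins (0.0815). In the S phase list 12 of 38 genes rose and 0 fell (13 and 1 adjusted over the list alone; camera adjusted p = 0.000154; adjusted p = 0.319 with an estimated correlation), including thymidylate synthase, TYMS, from 79.6 ± 2.76 to 120 ± 2.05 FPKM. In the list of G2 and mitosis 8 of 39 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0138; adjusted p = 0.577 with an estimated correlation), with an adjusted p of 0.0656 without PRMT1 guide replicate 1. CCNA2, cyclin A2, rose from 20.5 to 28.0 FPKM, whereas FOXM1, a transcription factor of mitotic genes, fell from 15.2 to 8.35 FPKM. Cytosolic ribosomal protein genes were higher in 23 of 78 cases and lower in 0 (27 and 0 adjusted over the list alone; camera adjusted p = 7.11e-06; adjusted p = 0.577 with an estimated correlation). RPL8 and RPL30, with the largest rises of that list, are both in the shifted stretches of chromosome 8, and the median of the list was 0.11 log2 units, or 0.0561 without PRMT1 guide replicate 3. RNA-binding proteins with arginine-glycine repeats, the class of proteins that PRMT1 methylates, were higher in 5 of 30 cases and lower in 0 (5 and 0 adjusted over the list alone; camera adjusted p = 0.0479; adjusted p = 0.319 with an estimated correlation). That call was kept in 11 of 20 settings. Among the losses were those without PRMT1 guide replicate 2 or 3 or control replicate 1 or 3 (adjusted p from 0.0546 to 0.0714).

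Replication-dependent histone genes fell, in 9 of 19 cases with 0 higher (14 and 0 adjusted over the list alone; camera adjusted p = 7.11e-06; adjusted p = 0.259 with an estimated correlation). H1-2 went from 16.2 ± 1.66 to 6.07 ± 1.12 FPKM and H2BC17 from 2.14 ± 0.478 to 0.451 ± 0.218 FPKM. These mRNAs mostly lack a poly(A) tail, the libraries were made from poly(A) RNA, and near-identical copies can share reads. Immediate early genes were lower in 8 of 18 cases and higher in 4 (9 and 4 adjusted over the list alone; camera adjusted p = 0.0279; adjusted p = 0.319 with an estimated correlation). The adjusted p was 0.0561 without PRMT1 guide replicate 3. Against EGR1 and FOS, ATF3 rose 2.17-fold (adjusted p = 0.119 for ATF3 with the most abundant transcript) and DUSP2 rose 2.66-fold.

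Interferon-stimulated genes were lower in 7 of 28 cases and higher in 4 (10 and 4 adjusted over the list alone; camera adjusted p = 0.0466; adjusted p = 0.503 with an estimated correlation). MX1, an antiviral GTPase, fell 1.69-fold to 5.33 FPKM (adjusted p = 0.126 for MX1 with the most abundant transcript), while IFITM3, a membrane protein that restricts viral entry, rose from 169 to 242 FPKM. The list kept its call in 14 of 20 settings. Among the losses were those without PRMT1 guide replicate 1 (adjusted p = 0.0618) or control replicate 1 (0.0791), and with mitochondrial genes left out (0.0579). Of the inflammatory targets of NF-kB 3 of 9 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0234; adjusted p = 0.319 with an estimated correlation; 0.0570 without PRMT1 guide replicate 2). CSF1, a macrophage growth factor, rose 1.84-fold and SOD2, in the shifted part of chromosome 6, rose 1.94-fold (adjusted p = 0.243 for SOD2 with the most abundant transcript).

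Lists bearing on drug response were not called by camera, although fry called drug efflux lower (adjusted p = 0.0141) and DNA repair higher (0.0257). Drug efflux transporters were lower in 3 of 7 cases and higher in 0 (3 and 0 adjusted over the list alone; camera adjusted p = 0.0540), led by the sterol transporter ABCG1, which fell from 5.79 ± 0.508 to 2.53 ± 0.0610 FPKM. That list gained a call without PRMT1 guide replicate 2 (adjusted p = 0.0284), control replicate 2 (0.0288), or control replicates 2 and 3 together (0.0160). Apoptosis regulators had 2 higher and 3 lower of 23 (2 and 4 adjusted over the list alone; adjusted p = 0.739), with the anti-apoptotic BCL2L1 at 35.4 against 27.9 FPKM and the initiator caspase CASP9 at 3.32 FPKM, 1.36-fold lower. Both lost their call when the most abundant transcript stood for the gene (adjusted p = 0.453 for BCL2L1 and 0.641 for CASP9) and without control replicates 2 and 3 (0.133 and 0.118). DNA repair genes had 4 higher and 0 lower of 29 (4 and 0 adjusted over the list alone; adjusted p = 0.114), led by FANCG in the shifted stretch of chromosome 9. Targets of p53 had 3 higher and 2 lower of 21 (3 and 2 adjusted over the list alone; adjusted p = 0.948). Markers of other cell types were almost unmeasured, with 1 tested gene each for leukocytes (CD14, 17.3 against 6.42 FPKM), fibroblasts (COL1A1, 1.14 against 1.69 FPKM, whose call was lost without PRMT1 guide replicate 1, control replicate 1 or control replicate 3, at COL1A1 adjusted p from 0.0514 to 0.0678) and endothelium (ESAM, 0.720 against 1.69 FPKM).

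**Figure D3:**
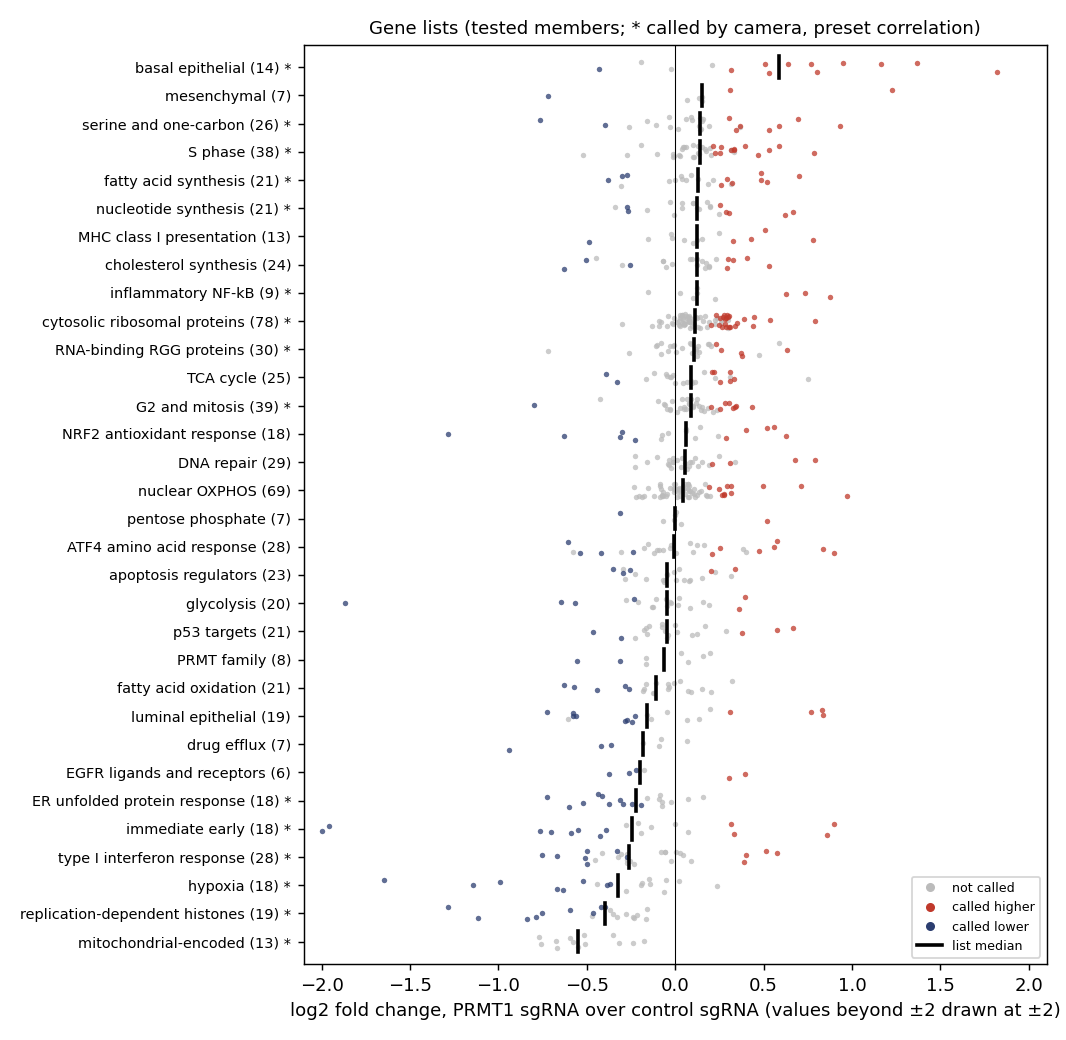
Log2 fold change of every tested member (points) of the 32 tested gene lists, with the number of tested members in brackets and the list median as a black bar. Red and blue points are genes called higher and lower by limma, and an asterisk marks the 15 lists called by camera with a preset correlation, of which 0 were called with an estimated correlation.

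Changes were also grouped along chromosomes, in a search chosen after the data had been seen. Among 8641 protein-coding genes with a mean of at least 3 FPKM, 5 blocks of neighbouring genes were shifted (coordinates on GRCh38.p14). On chromosome 8, from 98343975 to 145056030, 103 of 119 genes were called higher and 1 lower, with a median log2 fold change of 0.62 on the log2(FPKM + 1) scale (1.53-fold on that scale). On chromosome 9, from 34366666 to 38398661, 35 of 39 were higher and 1 lower (median 0.67, 1.59-fold on that scale). Smaller shifts covered chromosome 8 from 66429014 to 98045545 (19 of 43 higher, median 0.28) and chromosome 6 from 150865702 to 170584637 (18 of 28 higher, median 0.32). On chromosome X from 76173062 to 153935037, 66 of 119 genes were lower and 3 higher (median -0.29). Protein-coding genes outside the blocks had quartiles at -0.14 and 0.13. The medians of the chromosome 9 block were 0.649, 0.652 and 0.677 in the PRMT1 guide libraries and between -0.0379 and 0.0175 in the control libraries, each relative to the other controls. Libraries varied more in the proximal chromosome 8 block. Its medians were 0.267, 0.118 and 0.315 with the PRMT1 guide and between -0.0707 and 0.0536 in the control libraries. Blocks held 475 of the 11883 tested genes but 15.6% of the genes called higher and 5.82% of those called lower. PRMT1 itself lies outside the blocks, and the 22 protein-coding genes within 500 kb of it had a median log2 fold change of -0.07.

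**Figure D4:**
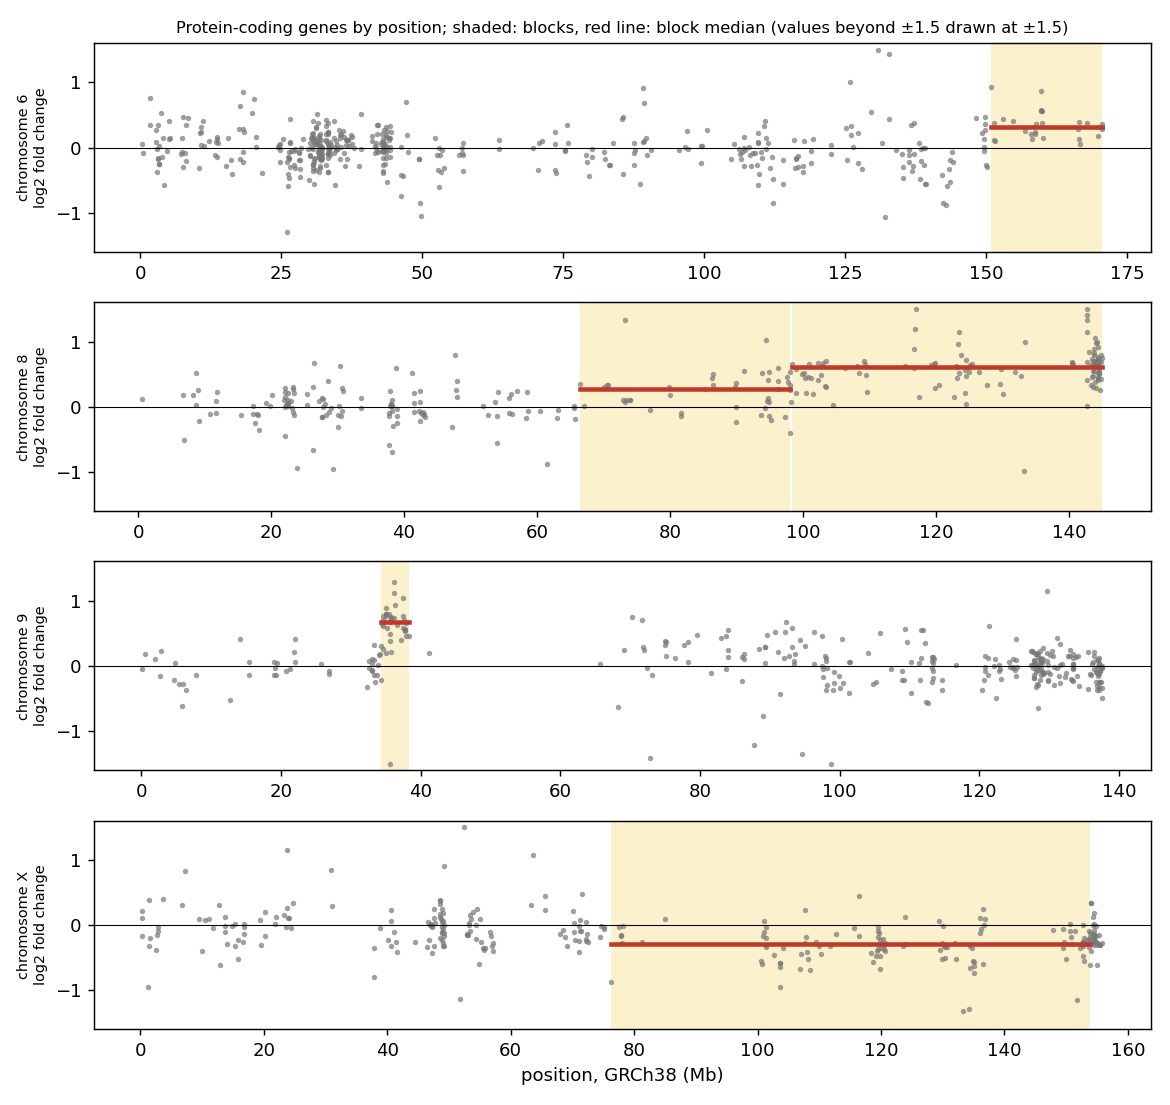
Log2 fold change of protein-coding genes with a mean of at least 3 FPKM (points) against position in Mb on chromosomes 6, 8, 9 and X, with the 5 blocks shaded and their medians as red lines. The block on chromosome 9 and the distal block on chromosome 8 lie at 0.67 and 0.62, and the block on chromosome X lies at -0.29.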

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

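The test of transcripts without a gene symbol was chosen after the data had been seen. Of 2498 such transcripts with a mean of at least 1 FPKM, limma called 2, with 216 at an unadjusted p under 0.05, and 1 of the 2 was higher than in the control libraries, in rows that no comparison by gene uses. That transcript, XM_011544809, measured 0.294 ± 0.139 FPKM in the control libraries and was higher with the PRMT1 guide (SD, n = 3 each; log2 fold change 2.08 ± 0.20, limma adjusted p = 0.0371). The lower one, XM_017000466, measured 0.118 ± 0.0378 against 22.0 ± 6.27 FPKM (limma adjusted p = 0.00491). Both were named because so few were called, after their values were seen, and their genes were not identified here.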

How the results depend on the processing

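Leaving out the genes of the blocks, leaving out mitochondrial genes and leaving out control replicates 2 and 3 together were chosen only after the data were seen. The log2 difference in PRMT1 FPKM kept its sign and was not called under any of the settings run, with values from -0.34 to -0.03 when 1 library was left out. Of 112 named genes called, 63 kept their call in every setting that applied to them, of up to 20, 88 kept it without each single library, and 0 reversed. Besides the genes named in the report as losing their call, with the most abundant transcript adjusted p was 0.315 for ERBB2, 0.110 for PFKM, 0.0930 for LDHA and 0.0579 for MUC1, and without control replicates 2 and 3 it was 0.148 for SOD2, 0.0654 for LDHA, 0.0647 for MX1, 0.0638 for ELOVL5, 0.0547 for ERBB2, 0.0514 for ESAM, 0.0642 for SCD and 0.158 for COL1A1. Without a filter on low values it was 0.0636 for SCD, 0.0580 for KRT5 and 0.0582 for FOLR1.

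Genes called with at least 2-fold change numbered 319 with a pseudocount of 0.1, which raises fold changes of low genes, and 110 with a mean of at least 5 FPKM, where fewer genes are tested. With the most abundant transcript in place of the sum, genes called numbered 1168 (genes called higher 613, genes called lower 555) and gene lists called 9; the cause was not tested. Without control replicates 2 and 3, genes called numbered 984 (genes called higher 553, genes called lower 431), with fewer samples. Leaving out 1 library gave from 1697 to 2279 genes called, 847 to 1151 genes called higher and 830 to 1133 genes called lower, the lowest without PRMT1 guide replicate 1, or for the lower genes control replicate 2. It gave 169 to 197 genes called with at least 2-fold change and 11 to 17 gene lists called.

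Genes that changed sign were uncalled in the analysis reported, and the cause was not tested. PSPH was at 0.01 and SHMT2 and PRMT2 at -0.244 and -0.063 with the most abundant transcript. SHMT2 was at -0.01 without mitochondrial genes. Without control replicates 2 and 3, PSPH was at 0.041, SHMT2 at -0.131, ACACA at -0.015, PRMT2 at -0.081 and PRMT5 at -0.043, and the median of the mitochondrial-encoded list was 0.0146. Leaving out 1 library gave -0.093 to 0.038 for PSPH, -0.025 to 0.094 for SHMT2 and -0.035 to 0.092 for PRMT2.

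With an estimated correlation, gene lists called were 0. By fry they were 18, which left out ribosomal proteins (0.0815), G2 and mitosis (0.123) and mitochondrial-encoded genes (0.223) and added fatty acid oxidation, the tricarboxylic acid cycle, MHC class I presentation, DNA repair, drug efflux and mesenchymal genes. The lists of the unfolded protein response, S phase, hypoxia, basal epithelium and ribosomal proteins were called in all 20 settings. Histones were called in all 19 that apply. All of these settings used camera at the preset correlation of 0.01. Over the settings, camera adjusted p ranged from 0.00230 to 0.0711 for serine and one-carbon metabolism, 0.0158 to 0.358 for fatty acid synthesis, 0.0165 to 0.102 for nucleotide synthesis, 0.0210 to 0.0791 for interferon, 0.0116 to 0.142 for NF-kB, 0.000420 to 0.0788 for G2 and mitosis, 0.0165 to 0.127 for RNA-binding proteins, 0.00682 to 0.0561 for immediate early genes and 5.18e-08 to 0.388 for mitochondrial-encoded genes. Without a filter on low values, oxidative phosphorylation, drug efflux (both 0.0302) and MHC class I presentation (0.0225) were called as well, and with equal totals the first of these (0.0333) and drug efflux (0.0454). Block medians ranged from 0.54 to 0.68 on distal 8q, 0.64 to 0.73 on 9p, 0.22 to 0.32 on proximal 8q, 0.24 to 0.38 on 6q and -0.32 to -0.27 on Xq.

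With replicate number as a block, genes called numbered 2081 (genes called higher 1031, genes called lower 1050). The labels do not say whether equal replicate numbers share a culture or day. No strong pairing was visible: residual correlations of equal numbers were -0.00974, -0.0604 and 0.0631, and the highest with another number were 0.0350, 0.149 and 0.0868. Residuals centred within such small groups cannot exclude a weak pairing. Read depth is unknown, so its effect on low genes was not measured.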

Other observations

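Receptors and ligands of the EGFR family moved apart. EGFR, which MDA-MB-468 cells express highly, rose from 132 ± 2.19 to 174 ± 11.1 FPKM (log2 fold change 0.40 ± 0.06, limma adjusted p = 0.00303), and ERBB2 fell from 16.2 ± 0.921 to 12.3 ± 0.771 FPKM (log2 fold change -0.37, limma adjusted p = 0.00852). Of 6 measured members 2 rose and 3 fell (2 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.559). Targets of the antioxidant factor NRF2 were split, with 5 higher and 5 lower of 18 (6 and 5 adjusted over the list alone; camera adjusted p = 0.739). FTH1, the ferritin heavy chain, rose from 1542 ± 85.5 to 2385 ± 74.2 FPKM, and the aldo-keto reductase AKR1B10 fell from 52.0 ± 3.70 to 20.7 ± 1.16 FPKM. In MHC class I presentation 4 of 13 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0862, fry adjusted p = 0.0236), with the immunoproteasome subunit PSMB10 rising 1.77-fold.

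Of the tests that follow, those of other splits of the samples, of S phase, of handling at harvest, of genes matched on GC content and length and of transcript shares were chosen only after the result was seen, as were the search for blocks and the interval conditions on the ERK and handling tests. Bootstrap intervals of medians resample genes as if independent and leave out the spread between libraries. The 5 shifted chromosome blocks may reflect a copy number difference between the cell populations that received each guide. Some genes of the 8q distal and 9p blocks, low or not protein-coding, took no part in finding them. On log2(FPKM + 0.1), not the main log2(FPKM + 1), these held-out genes had a median log2 fold change of 0.502. Of 48 such genes 42 lay above 0 (95% bootstrap interval of the median 0.321 to 0.646). The median of the genes that found the blocks was 0.675 on the same scale. On that scale the held-out median for the 6q, 8q proximal and Xq blocks, signed by block, was 0.199 (79 genes, interval 0.044 to 0.321) against 0.306. This leaves those blocks open, the proximal 8q block most of all with 0.035. A bias by GC content or transcript length is argued against by 157 genes outside the blocks matched on both. On log2(FPKM + 1) their median was 0.034 (interval -0.009 to 0.063), against 0.627 for the 8q distal and 9p genes. Removing a trend on both (median then 0.621) tests little, as its R2 was 0.0066. RNA alone cannot tell a gained segment from regional regulation. Nor, as a hypothesis, can it tell a difference between cell clones present before editing from an effect of the PRMT1 guide. Of the 10 splits of the 6 samples 1, the real one, gave 5 blocks while the others gave at most 1, too few splits for a share under 0.05. The blocks in those others had medians of 0.31 and 0.27 in size. The proximal 8q and Xq blocks, at 0.28 and -0.29, were no larger than that range. Each of the others mixes libraries of both guides, which shrinks a real block shift, so their low counts do not measure chance.

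Replication-dependent histone genes were lower (median log2 fold change -0.397, all 19 below 0; adjusted p = 0.259 with an estimated correlation), and 12 of 38 S phase genes were called higher and 0 lower (adjusted p = 0.319 with an estimated correlation). Fewer cells in S phase would lower the S phase list, but its median was 0.141 (interval 0.081 to 0.219). By fry the list was higher (adjusted p = 0.00792). It was known to be higher when this test was chosen, so the test is no separate check of the explanation. A lower copy number of the histone cluster as the whole cause is argued against by the other 22 protein-coding genes there, with a median of -0.081 (interval -0.187 to -0.048; 5 called lower and 0 higher), above the bound set beforehand, which lay midway between 0 and the histone median. Less carry-over of RNA without a poly(A) tail may contribute. The 7 measured RNAs of that kind, of 22 listed, had a median of -0.327 (interval -0.595 to 0.315). However, 0 of them were called lower and 1 was called higher. That RNA, RNU5A-1 at 1.32, was singled out after its value was seen. Less carry-over cannot be told apart from an effect of the PRMT1 guide on histone mRNA, which was not tested.

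EGR1 and FOS fell most among immediate early genes, and 2 technical or signalling explanations stay open. Lower ERK signalling was to be argued against if the median of an ERK output list lay above 0 or most called members were higher. Both were met (median 0.405, 6 called higher and 2 lower of 10), but a further condition, that the 95% interval lie above 0, was added after this value had been seen, and the interval from -0.424 to 0.513 includes 0. Called members went both ways, with DUSP4 at -0.95 and DUSP6 at -0.77, both named after their values were seen, so the list decides nothing. Handling at harvest that moves these genes alike allows at most 10% of called members to be higher. The share was 33.3% (4 of 12), which met the bound stated for arguing against this explanation. An exact 95% interval, from 9.92% to 65.1%, was likewise required only after the value had been seen, and it reaches 10%. That interval treats genes as independent. Of the 4 higher genes 1, MYC (log2 fold change 0.33), lies in a shifted chromosome block, and the 12 include EGR1 and FOS themselves. The explanation therefore stays open.

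Of the 10 splits of the 6 samples, 1, the real one, gave 2820 called genes, and the highest of the others gave 2. For gene lists 1 split, the real one, gave 15, and the others gave from 3 to 8. With 10 splits no share under 0.05 can be reached. Every other split mixes libraries of both guides, which dilutes a real difference and widens the spread within groups. Low counts in those splits are therefore partly fixed in advance. A shift of transcript usage within genes was tested on 9378 transcripts of 4082 genes: limma called 0, with 653 at an unadjusted p under 0.05, while other splits called up to 4 and had up to 517 at an unadjusted p under 0.05. In PEG10 the transcript NM_001040152 held 75.7% of the gene's FPKM with the PRMT1 guide and 1.94% with the control guide, and NM_001184962 held 0.654% and 64.5%, a pair singled out after their values were seen.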
